A study of Mus musculus with 3 samples.

How the data were processed

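DNase-seq measures where chromatin is open: nuclei are treated with DNase I, an enzyme that cuts exposed DNA, and the cut ends are sequenced, so that places with many sequence tags mark hypersensitive sites. The data collected were 3 lists of such sites, 1 from each of 3 mouse fat depots: epididymal white fat (eWAT), inguinal white fat (iWAT) and brown fat (BAT). Per the labels' protocols, the brown fat was pooled from several depots of the upper body. The stromal-vascular cells of each depot, which hold the fat cell precursors, were taken from male NMRI mice of 4 to 5 weeks and turned into fat cells in culture. The medium held 30 nM insulin, 10% serum and 1 µM rosiglitazone, a drug that activates the fat cell regulator PPARγ. Cultures were harvested on day 8 after plating, and only those with more than 50% differentiated cells were used, per the labels' protocols. Nuclei were digested with 120 U/ml DNase I.

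The authors deposited 1 list of called sites per depot, and the submitters' processing notes name STAR, HOMER and the genome build mm9 without giving roles, versions or settings. The column names of the deposited lists are those of HOMER's findPeaks. For each site the authors' file holds a normalized tag count, which is treated here as a signal, and which is relative to a library total that the file does not state. It also holds a deposited peak score in whole numbers, a focus ratio (a fraction between 0 and 1 that gauges how sharply tags are centred), a fold (ratio) of the site's tag density over its surroundings with a p-value, and a clonal fold. In each deposited list the minimum fold over the surroundings was 4, and the highest p-values were 9.98e-05 in eWAT, 9.9e-05 in iWAT and 9.76e-05 in BAT. A minimum of this kind leaves out sites whose surroundings are also rich in tags. Each depot has its own list. Whether a library pooled several cultures is not given in the sources used here.

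The normalized tag counts of each library were whole multiples of 1 step, which is what 1 tag is worth: 0.595 in eWAT, 0.985 in iWAT and 0.857 in BAT. With a tolerance of 0.05 (0.005 for values below 10), 99.9%, 99.4% and 99.5% of the values were whole multiples. The total to which the libraries were scaled is not given in the sources used here. If it was the same for all, the eWAT library was 1.66 times and the BAT library 1.15 times as deep as the iWAT library. The lowest score was 11 in eWAT, 9 in iWAT and 10 in BAT. If 1 score unit is worth 1 tag, which the sources used here do not state, this equals 6.54, 8.87 and 8.57 normalized tags. The lowest normalized tag counts were smaller, with 4.16 in eWAT, 5.91 in iWAT and 6 in BAT.

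Coordinates are given as the deposited lists give them, in mm9. On 10 of the 21 chromosomes the last site lay beyond the last gene of the GRCm38 gene table at hand, by up to 7.19 Mb on chromosome 7, so that table was not used for positions. An mm9 gene annotation and genome sequence were not used here. For this reason the 16 gene lists and 22 motifs that were fixed before the data were examined, and the promoter share of sites, were not analysed here, and no site is assigned to a gene. The rule for this case, also fixed beforehand, named per depot the 10 restricted regions with the highest tag count and the 3 windows of 100 kb (on a grid from the chromosome start) with the most restricted regions, plus the 5 windows with the most regions common to all depots. Ties between windows were ordered by summed tag count, a choice made later.

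A site was counted as found in another list if it overlapped a site there by at least 1 bp. Sites of the 3 lists that overlapped or touched were merged into regions, which fall into 7 classes by the lists that hold them. A site or region is called restricted if no other list holds a site there. A strong site is in the top 25% of its own list by the authors' tag count; tag counts were used to rank sites only within a list. Expected overlap came from 100 placements of the sites at random positions between the first and the last site of their chromosome. With 1 library per depot there is no replicate error, so no test between depots was made and no p-value between depots is given. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, and neighbouring sites are not independent. Alternatives to the overlap, the site width, the list length, the definition of strong and the chromosomes used were also fixed beforehand. The overlap, merging and restricted-site code was run on simulated lists of 99297 regions with known classes, and 100% were recovered. The simulated regions lay in separate stretches of 1 kb, and shared sites always overlapped. The run thus checks for coding errors only, not how closely spaced sites of the real lists are classed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.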

Results

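Open chromatin was mapped by DNase-seq in fat cells grown from 3 mouse depots, with 1 library from each. The list from epididymal white fat (eWAT), a depot inside the abdomen, held 60974 hypersensitive sites. The list from inguinal white fat (iWAT), a depot under the skin, held 63214 sites, and the list from brown fat (BAT), the heat-producing depot, held 48308. Sites were 220 bp wide in eWAT and 222 bp wide in iWAT and BAT, apart from 1 site per list, and together they covered 13.4, 14.0 and 10.7 Mb. The median site held 16 tags in eWAT, 14 in iWAT and 14 in BAT, counted in steps of the normalized tag count. The median tag density was 7.46, 9.91 and 9.23 times that of the surroundings, so that enrichment over local background was lowest in eWAT. There were no replicates of any depot, so every difference described here is between single libraries.

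The first comparison asked how far the landscapes of open chromatin of the 3 depots coincide. More than 50% of the sites of a depot were found in another depot in 4 of the 6 directions, and each pair of depots coincided to a similar extent. Of the eWAT sites, 58.0% (95% interval 57.7 to 58.4) overlapped an iWAT site and 48.6% (48.2 to 49.0) a BAT site. Of the iWAT sites, 56.0% (55.6 to 56.4) overlapped an eWAT site and 49.0% (48.6 to 49.4) a BAT site. Of the BAT sites, 61.3% (60.9 to 61.7) overlapped an eWAT site and 64.2% (63.7 to 64.6) an iWAT site. Sites placed at random gave 1.11% for eWAT with iWAT, 0.976% for eWAT with BAT and 0.998% for iWAT with BAT.

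The mean of both directions was 57.0% for the white depots eWAT and iWAT, 56.6% for iWAT and BAT, and 54.9% for eWAT and BAT. By base pairs, the shared part of the covered sequence was 26.7%, 25.6% and 25.1%. The order of the pairs depended on how the lists were limited. With lists of equal length (48308 sites each) the means were 58.5%, 57.4% and 56.2%. When all lists were limited to the same minimum score of 8.87 normalized tags, a setting chosen after seeing the data, they were 57.1%, 56.6% and 57.2%, and the pair of eWAT and BAT was no longer the lowest. That limit assumes the same scaling total in all libraries and a score counted in tags. It left lists of unequal length, with 39039 sites in eWAT, 63214 in iWAT and 42606 in BAT.

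The sites of the 3 lists merged into 99297 regions. A common set of 25009 regions (25.2%, 95% interval 24.9 to 25.5) was listed in all 3 depots, and 23157 regions (23.3%) were listed in exactly 2. Tag counts were not at hand where a list held no site, so absence from a list does not show closed chromatin. The other 51131 regions (51.5%) were listed in a single depot: 19482 in eWAT, 20317 in iWAT and 11332 in BAT. The order of these numbers followed the length of the lists: with lists of equal length they were 13675, 13096 and 14278, and with a common minimum score 7782, 26450 and 10187. Common sites were the stronger ones within every list. Their median tag count was 12.5 in eWAT against 7.73 for the restricted sites, 19.7 against 10.8 in iWAT, and 15.4 against 10.3 in BAT. When sites within 200 bp of each other were merged as well, the common set rose to 30895 regions (34.6% of 89173).

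**Figure D1:**
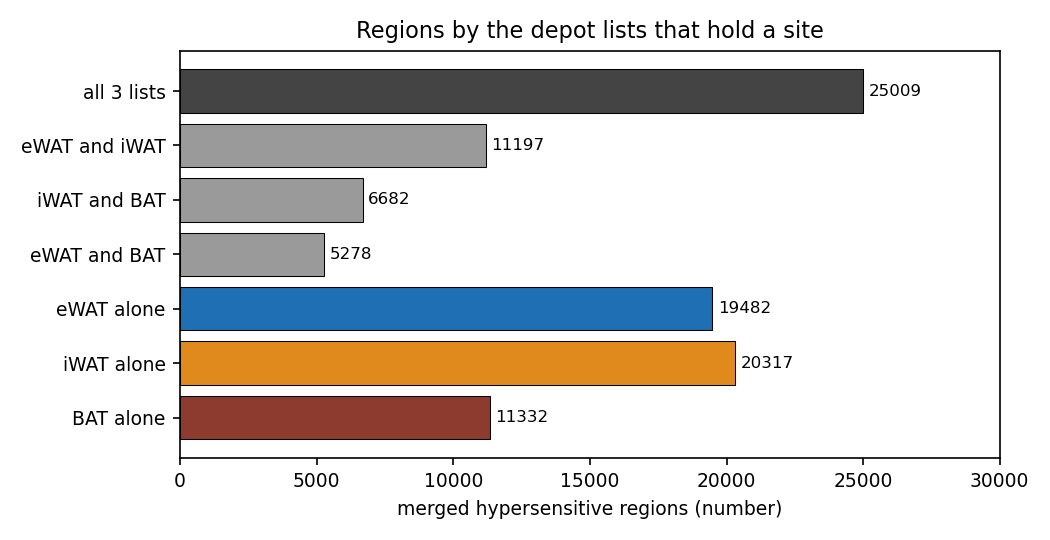
Number of merged hypersensitive regions (horizontal axis) for each combination of depot lists that holds a site. The dark bar is the set common to all 3 depots (25009 regions), the light grey bars are regions in exactly 2 lists, and the coloured bars are regions in a single list (19482, 20317 and 11332), at the deposited list lengths of 60974, 63214 and 48308 sites.

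Within the common set, the ranking of the regions by tag count was also related between depots. Over the 24988 common regions with exactly 1 site from each list, Spearman's rho across regions was 0.73 for eWAT and iWAT, 0.68 for iWAT and BAT and 0.66 for eWAT and BAT; regions are not independent replicates, and no error between libraries can be given. Of the 2498 regions in the top 10% of eWAT, 66.8% were also in the top 10% of iWAT and 63.6% in that of BAT. The top 10% of iWAT and of BAT shared 61.8%, where unrelated ranks would give 10%. The common region with the highest summed ranks, singled out after its values were seen, lay on chromosome 2 at 98507178 to 98507400 and held 468, 783.2 and 663 normalized tags in eWAT, iWAT and BAT, each relative to its own library. Its tag density was 6.34, 6.83 and 6.66 times that of its surroundings. The next lay on chromosome 9 at 35112912 to 35113136, with 430.6, 731 and 575.6 normalized tags, and stood 60.1, 66.4 and 58.6 times above its surroundings. Of the 5 highest common regions, 3 lay between 98502746 and 98507400 on chromosome 2 and 1 at 3000003 to 3000226 on chromosome 9. The clonal folds of these 5 regions ranged from 0.27 to 0.52, where the median site of each list had 0.97. Within each list's 10 highest restricted regions the clonal fold fell as tags rose, in BAT from 0.89 at 56 tags to 0.64 at 216. A low clonal fold thus goes with the high tag counts for which these 5 regions were picked. It is no separate sign that they differ from other sites. No region was left out for its clonal fold or its fold over the surroundings, and the cause of these values was not tested.

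The windows of 100 kb with the most common regions were spread over 5 chromosomes. The window from 125100001 to 125200000 on chromosome 2 and that from 55000001 to 55100000 on chromosome 18 each held 11 common regions. The window from 23600001 to 23700000 on chromosome 13 and that from 96000001 to 96100000 on chromosome 3 each held 10. The window from 135600001 to 135700000 on chromosome 4 held 9. In the chromosome 18 window nearly every site was common: eWAT and iWAT each listed 12 sites and BAT 13.

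The second comparison asked whether the white depots share more open regions with each other than with brown fat. Of the 23157 regions in exactly 2 lists, 11197 (48.4%) were in eWAT and iWAT, 6682 (28.9%) in iWAT and BAT, and 5278 (22.8%) in eWAT and BAT. The same order held among regions with a strong site, that is, a site in the top 25% of its list: 2245, 1697 and 1315 regions. The pair of white depots thus made up 42.7% (95% interval 41.4 to 44.1) of the strong regions in exactly 2 lists. The excess of the white pair depended on the length and the threshold of the lists. With lists of equal length the 3 classes held 6917, 6317 and 5738 regions, and the ratio of the white pair to the next was 1.09 (95% interval 1.06 to 1.13) in place of 1.68 (1.63 to 1.73). With the same minimum score in all lists, iWAT and BAT were the largest pair, with 8617 regions against 7453 for eWAT and iWAT, and with 1939 against 1798 strong regions, but iWAT was then by far the longest list (63214 sites against 39039 in eWAT and 42606 in BAT). With lists of equal length, a setting fixed beforehand, the strong regions numbered 2138 for eWAT and iWAT and 1826 for iWAT and BAT. The ratio was 1.17 (95% interval 1.10 to 1.25), but the white lists then still held more strong sites than BAT. When the number of strong sites was made the same as well, a setting chosen after seeing the data, they numbered 1514 and 1509, a ratio of 1.003 (95% interval 0.934 to 1.08).

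The third comparison asked which sites are listed in a single depot. Fewer than 10% of the strong sites were restricted when ranked by tag count. Of the 15243 strong eWAT sites, 1302 (8.54%, 95% interval 8.103 to 8.997) overlapped no site of the other depots, against 1505 of 15803 in iWAT (9.52%, 9.07 to 9.99) and 962 of 12077 in BAT (7.97%, 7.49 to 8.46). Ranked by fold over local background instead, 18.4%, 19.6% and 11.5% of the strong sites were restricted. By tag count, 71.6%, 69.6% and 74.4% of the strong sites were found in both other lists. Most of the strong restricted sites had a site of another depot close by without overlapping it: 77.1% in eWAT, 74.6% in iWAT and 74.8% in BAT had one within 1 kb, where random placement gave 5.59%, 5.71% and 6.06%. Random placement ignores where sites are dense, so it is a low baseline. Within 10 kb of a common region lay 47.7%, 45.8% and 49.0% of the strong restricted sites, against 17.3%, 17.2% and 17.3% at random. Strong sites with no site of another depot within 1 kb numbered 298 in eWAT (1.96% of strong sites, 95% interval 1.74 to 2.19), 383 in iWAT (2.42%, 2.19 to 2.68) and 242 in BAT (2.004%, 1.76 to 2.27).

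**Figure D2:**
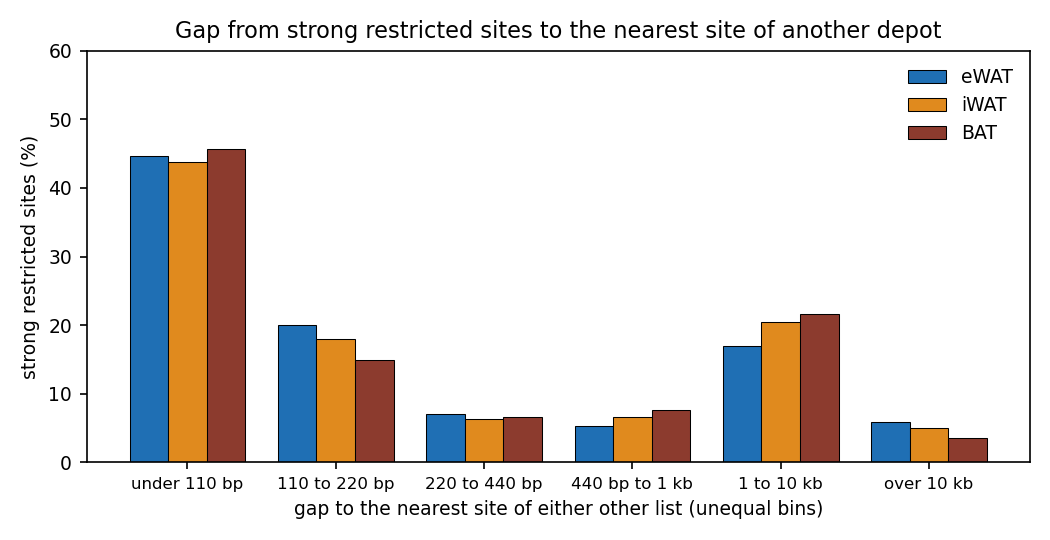
Share of the strong restricted sites of each depot (vertical axis, percent) by the gap to the nearest site of either other depot (horizontal axis, unequal bins). In each depot the largest group lay under 110 bp away, with 44.7% in eWAT, 43.7% in iWAT and 45.7% in BAT, and 5.91%, 5.05% and 3.53% lay over 10 kb away.

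The share of restricted sites rose steeply from strong to weak sites in each depot. In the top 10% of the lists it was 5.12% in eWAT, 5.60% in iWAT and 5.69% in BAT, and the 95% intervals overlapped. In the lowest 10% it was 63.9%, 63.4% and 45.9%. The BAT list was the shortest and was matched against longer lists, so its lower share is not a like comparison. In the top 10%, 0.656% of eWAT sites (95% interval 0.469 to 0.892), 0.965% of iWAT sites (0.739 to 1.24) and 1.26% of BAT sites (0.967 to 1.62) had no site of another depot within 1 kb.

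**Figure D3:**
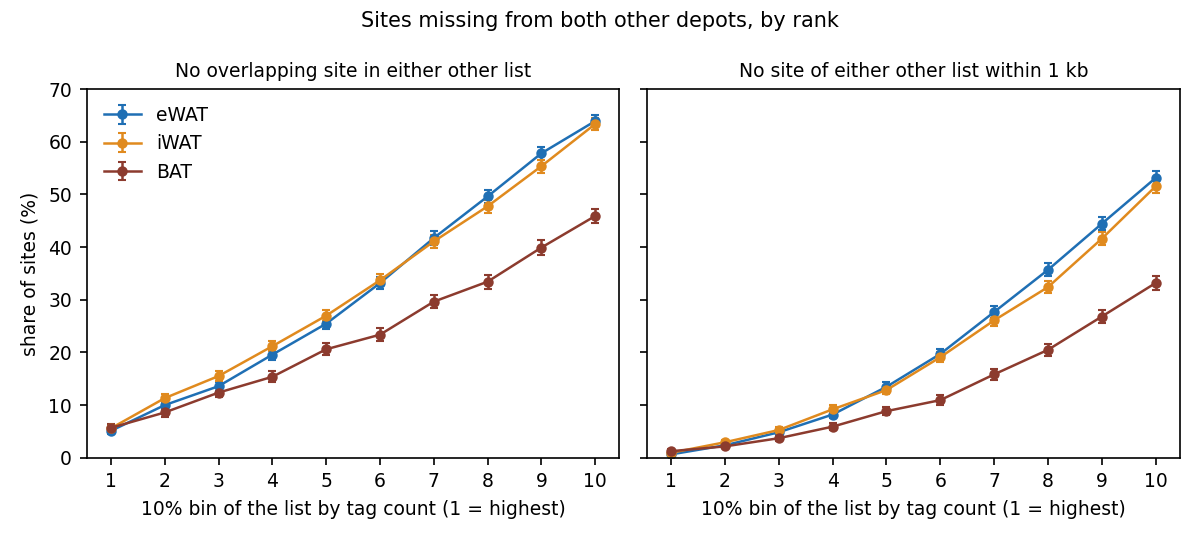
Share of sites (vertical axis, percent) that no other depot shares, by 10% bin of each list ranked by tag count (horizontal axis, 1 is the highest), counting overlap (left) or any site within 1 kb (right). Points are shares of the sites of 1 library and bars are exact 95% intervals for counting error. In each depot the share rises from the first to the last bin, to 63.9%, 63.4% and 45.9% on the left. The lists differ in length, with BAT the shortest, so the depots are not directly comparable.

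The restricted regions with the highest tag counts often lay beside a site of another depot. Of the 10 highest per depot, 8 in eWAT, 5 in iWAT and 10 in BAT had a site of another depot within 1 kb. In BAT the region on chromosome 15 at 62160045 to 62160267 held 66.8 normalized tags (78 tags), 20.2 times above its surroundings, and the nearest site, in eWAT, lay 80 bp away. The BAT region on chromosome 8 at 42456141 to 42456363 held 54.8 normalized tags and had an eWAT site 31 bp away, and the region on chromosome 6 at 52138942 to 52139164, with 48.8 normalized tags, had an eWAT site 37 bp away. In eWAT the region on chromosome 14 at 106452009 to 106452229 held 42.8 normalized tags and had a BAT site 112 bp away. In iWAT the region on chromosome 15 at 9794833 to 9795055 held 69.0 normalized tags and had a BAT site 99 bp away. The regions at the top of each list's restricted set lay near the start of chromosome 11, at 3074113 to 3074333 in eWAT (88.6 normalized tags), 3004473 to 3004695 in iWAT (157.6) and 3001158 to 3001380 in BAT (185). They stood 5.7, 4.13 and 5.42 times above their surroundings, and the BAT region had an iWAT site 254 bp away. The nearest site to the eWAT and iWAT regions was a BAT site, 18.9 and 2.47 kb away. Their clonal folds were 0.73, 0.71 and 0.64 in eWAT, iWAT and BAT, where the median site of each list had 0.97. Since the clonal fold fell as the tag count rose, these values are no separate sign beside the high tag counts. Each list thus held a high site near the start of chromosome 11. A lack of overlap there does not by itself show a difference between depots, and its cause was not tested.

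The iWAT list held 5 of its 10 highest restricted regions more than 1 kb from any site of the other depots. Of these, 2 lay near the start of chromosome 11, at 3004473 to 3004695 and 3053947 to 3054169, and both such regions of eWAT lay near the start of a chromosome, on chromosome 11 at 3074113 to 3074333 and on chromosome 9 at 3037928 to 3038148. The other 3 iWAT regions included chromosome 16 from 77594179 to 77594401, with 68.0 normalized tags and the nearest site 8.27 kb away in eWAT, and chromosome 16 from 23982576 to 23982798, with 65.0 normalized tags and the nearest site 6000 bp away in eWAT. The last lay on chromosome 3 from 5210113 to 5210335, with 63.0 normalized tags and the nearest site 18.8 kb away in BAT. These 3 regions stood 5.81, 4.89 and 4.55 times above their surroundings, where the lowest value in each list was 4 and the median of iWAT 9.91.

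Strong sites that had no site of another depot within 1 kb and stood at least 6 times above their surroundings were taken as the clearest single-depot sites, a criterion chosen after the values were seen. There were 166 in eWAT (1.09% of strong sites, 95% interval 0.930 to 1.27), 192 in iWAT (1.21%, 1.05 to 1.40) and 92 in BAT (0.762%, 0.615 to 0.933). Of these, 74 in eWAT, 64 in iWAT and 22 in BAT had no site of another depot within 10 kb. The highest in eWAT lay on chromosome 16 at 75961553 to 75961773, with 44 tags, 26.4 times above its surroundings and 26.6 kb from the nearest site of another depot. The next in eWAT, on chromosome 5 at 10032467 to 10032687, held 43 tags and was 77.6 kb from the nearest site of another depot. In iWAT the highest, on chromosome 10 at 87368962 to 87369184, held 39 tags, stood 7.7 times above its surroundings and was 3.81 kb from the nearest BAT site. The next in iWAT, on chromosome 6 at 65941696 to 65941918, held 38 tags, stood 18.6 times above its surroundings and was 19.1 kb from the nearest eWAT site. In BAT the highest, on chromosome 4 at 40794176 to 40794398, held 43 tags at 6.39 times above its surroundings and was 1.38 kb from the nearest eWAT site. The next in BAT, on chromosome 17 at 33921827 to 33922049, held 42 tags at 6.53 times above its surroundings and was 1.35 kb from the nearest iWAT site. Both BAT sites thus lay close to the limits of 6 times and 1 kb.

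Restricted regions were also counted in windows of 100 kb. The windows named here were picked for the most restricted regions of 1 list. A larger number of sites in that list than in the others therefore follows from the choice. The window with the most iWAT-restricted regions ran from 96100001 to 96200000 on chromosome 11 and held 11 of them, with 15 iWAT sites in all against 7 in eWAT and 7 in BAT. Other iWAT windows ran from 165500001 to 165600000 on chromosome 1 and from 99600001 to 99700000 on chromosome 15, with 9 restricted regions each. The chromosome 1 window had 12 iWAT sites against 2 in eWAT and 4 in BAT. In BAT the windows with the most restricted regions lay on chromosome 3 from 107500001 to 107600000, on chromosome 14 from 68200001 to 68300000 and on chromosome 16 from 91700001 to 91800000, with 7 each. BAT listed 13, 11 and 11 sites there, against 8, 4 and 7 in eWAT and 11, 6 and 6 in iWAT, and the first window also held 6 regions restricted to iWAT. In eWAT they lay on chromosome 11 from 116300001 to 116400000, on chromosome 7 from 95400001 to 95500000 and on chromosome 19 from 16200001 to 16300000, with 8 each. In the eWAT window on chromosome 11, eWAT listed 11 sites, iWAT 7 and BAT 3. Most restricted sites in these windows were not strong. In the order in which the windows are named, strong ones numbered 2, 1 and 1 in eWAT, 1, 2 and 1 in iWAT, and 3, 3 and 1 in BAT. A site of another depot lay within 1 kb of 3, 2 and 3 of the restricted sites in the eWAT windows, 6, 3 and 2 in the iWAT windows, and 3, 3 and 3 in the BAT windows. The numbers of restricted regions depended on the setting. With sites within 200 bp merged, the eWAT windows held 6, 7 and 5, the iWAT windows 8, 7 and 9, and the BAT windows 5, 5 and 4. With lists of equal length the iWAT windows held 5, 6 and 6 restricted regions and the eWAT windows 7, 8 and 5. With a common minimum score the eWAT windows held 7, 3 and 4. With the top 50% of each list the eWAT windows held 5, 4 and 2, the iWAT windows 3, 6 and 3, and the BAT windows 6, 5 and 3.

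**Figure D4:**
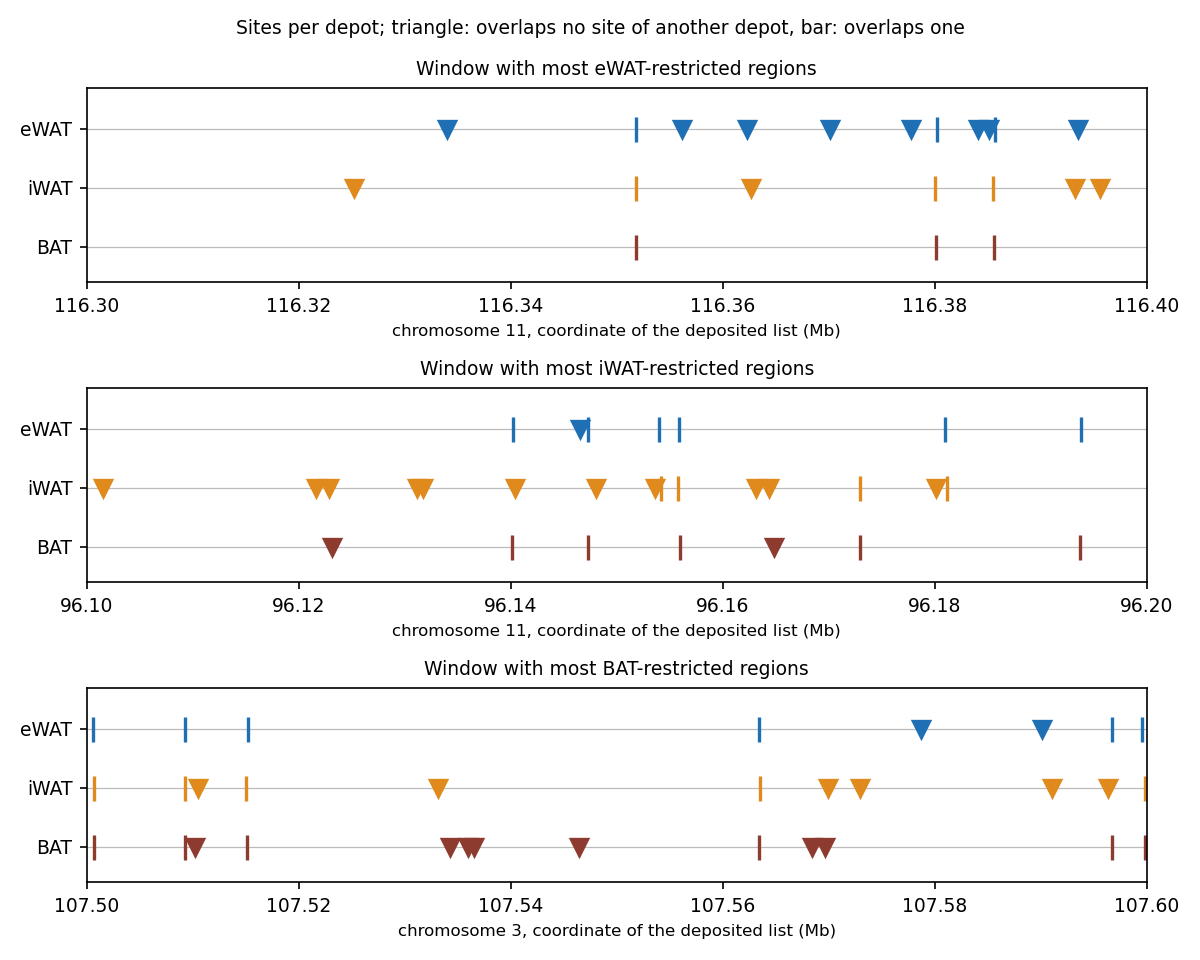
Positions of all sites (horizontal axis, Mb, mm9) in each depot's list (rows) for the 100 kb window with the most restricted regions of eWAT (top), iWAT (middle) and BAT (bottom). Triangles are sites that overlap no site of another depot and bars are sites that do; the iWAT window shows 11 iWAT triangles.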

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

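The settings with a common minimum score with sites strong in both lists, and with the same number of strong sites for the pairs of depots were chosen after seeing the data. The mean overlap of eWAT with iWAT, eWAT with BAT, and iWAT with BAT is given in that order. A reciprocal overlap of 50% gave 47.8%, 46.3% and 47.3%, sites resized to 200 bp 55.6%, 53.6% and 55.2%, the top 50% of each list 59.7%, 57.2% and 58.4%, lists of equal length 58.5%, 56.2% and 57.4%, and a common minimum score 57.2% for eWAT with BAT. The order of the pairs held under these settings except the last. Of the region classes, the top 50% of each list held 13074 common regions, 5766 in eWAT and iWAT, 3159 in iWAT and BAT, 2572 in eWAT and BAT, 9072 in eWAT alone, 9605 in iWAT alone and 5349 in BAT alone, with fewer sites by construction. Lists of equal length left 6917 regions in eWAT and iWAT and 13096 in iWAT alone, where BAT alone held 14278. A common minimum score left 7453 in eWAT and iWAT, 3108 in eWAT and BAT, and 7782 in eWAT alone, with 39039 sites left in eWAT, 63214 in iWAT and 42606 in BAT. The share of strong sites that were restricted, in eWAT, iWAT and BAT, was 5.10%, 5.60% and 5.69% for the top 10%, 14.8%, 16.1% and 12.5% for the top 50%, 18.4%, 19.6% and 11.5% when ranked by fold over local background, and 1.96%, 2.42% and 2.004% with no site within 1 kb. It was 7.50% in eWAT and 8.20% in iWAT with the same number in each list, 8.50% in BAT against lists of equal length, and 6.79% in eWAT and 10.8% in iWAT with a common minimum score. Strong regions in eWAT and iWAT, iWAT and BAT, and eWAT and BAT numbered 585, 497 and 442 for the top 10%, 6321, 4045 and 3115 for the top 50%, 898, 698 and 578 if strong in both lists, and 616, 564 and 516 if strong in both lists with the same number in each list. The other 47 values of these results moved by less than their counting interval (shares) or 1.5 times (counts). With sites within 200 bp merged, 2 of the 10 named restricted regions of eWAT, 5 of iWAT and 1 of BAT stayed restricted. Shorter lists and stricter definitions of strong lower the counts by construction, and for the other values the cause was not tested. What the depth limits was not tested, since the totals of the libraries are not given in the sources used here. The alternatives for promoter shares, gene lists and motifs were not run. No paired analysis was possible because each depot has 1 library.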

Other observations

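The tests of the calling threshold, of the shorter BAT list and of the local-background filter at isolated sites, and the settings with sites strong in both lists, and with the same number of strong sites for the pairs of depots (also with lists of equal length), were chosen after related values had been seen. The common class took between 23.8% (chromosome 15) and 26.9% (chromosome 7) of the regions of the 19 autosomes, and 22.8% (95% interval 21.0 to 24.7) of the 2073 regions on the X chromosome. The share of BAT-restricted regions ranged from 10.2% (chromosome 14) to 12.7% (chromosome 12), and was 11.3% on the X chromosome. The Y chromosome held 90 regions, of which 37 (41.1%) were common and 14 (15.6%) were in eWAT and BAT, above the ranges of the autosomes (4.70% to 5.93% for eWAT and BAT).

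The first pattern is the set of strong sites missing from both other lists. The highest share of these sites with a neighbour of another depot within 1 kb was 77.1%, between the bounds of 50% and 90% set beforehand, so the same site called at a shifted position may account for most but not all of the pattern. Most of these neighbours lay at short range: 64.7%, 61.7% and 60.7% of the strong restricted sites had one within 220 bp in eWAT, iWAT and BAT. Of the strong common sites, 14.7%, 14.1% and 15.9% had a second site of another depot within 1 kb. These are not a like baseline, since the distance differs and the sites that overlapped the common site were not counted. At most 33.3% of the strong restricted sites stood under 6 times above their surroundings, below the bound of 50% set beforehand for the local-background filter. By depot it was 31.3% in eWAT, 27.3% in iWAT and 33.3% in BAT, against 9.45%, 3.78% and 4.24% of the strong common sites. Of the restricted sites with no neighbour within 1 kb, 44.3%, 49.9% and 62.0% stood under 6. The fold was known only in the list that holds the site, not in those that lack it. The test thus cannot decide, and the filter stays open. A place near the calling threshold also stays open, since the share with no neighbour within 1 kb in the top 10% was as low as 0.656% and its 95% interval reached below 1% in each list. With 1 library per depot, a difference between depots cannot be told apart from a difference between single libraries.

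The second pattern is the gathering of restricted sites in the same 100 kb windows. When the restricted status was reassigned 100 times among sites of the same list and rank, the windows with 5 or more restricted sites numbered 220 in eWAT against at most 219, 295 in iWAT against at most 277, and 54 in BAT against at most 40, so site density and rank alone are argued against, in eWAT by 1 window only (the lowest ratio to the mean of the reassignments was 1.15). Windows with 2 or more strong restricted sites numbered 110, 154 and 89 against at most 96, 120 and 64 (lowest ratio 1.47), which argues against weak sites alone. It cannot decide whether these windows hold many sites of 1 library at every strength, since strong sites would then gather too. With strong sites that had no neighbour of another depot within 1 kb, iWAT had 24 such windows against at most 15 and BAT 17 against at most 6, while eWAT had 8 against at most 8 (lowest ratio 1.85), so sites called at shifted positions remain open for eWAT. The local-background filter was not tested for these windows, and 49.9% of such sites in iWAT and 62.0% in BAT stood under 6 times above their surroundings, so it stays open, as does an untested difference between depots or between single cultures.

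The third pattern is the excess of regions shared by the white depots alone. It fell from a ratio of 1.68 to 1.09 (95% interval 1.06 to 1.13) with lists of equal length, so the shorter BAT list may account for most of it. Cutting the lists to equal length also removed the weakest sites of the white depots. This setting thus cannot tell list length apart from weak sites. Weak sites alone stay open: the ratio was 1.29 (1.16 to 1.42) among regions strong in both lists, but the strong sets differ in size with the lists, and with the same number of strong sites in each list it was 1.09 (0.973 to 1.23), or 1.095 (1.02 to 1.18; 1556 against 1421 regions) if a strong site in 1 list sufficed. For regions with a strong site the ratio was 1.17 (1.10 to 1.25) with lists of equal length, where the white lists held more strong sites than BAT. With lists of equal length and the same number of strong sites in each, it was 1.003 (0.934 to 1.08). These lists thus do not settle whether the white depots resemble each other more than they resemble brown fat. They also cover only fat cells grown in culture, all with 1 µM rosiglitazone, and not the depots themselves.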
